A study of Danio rerio with 18 samples.

How the data were processed

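Whole zebrafish embryos of 3 conditions and 2 stages were assayed by enriched SLAM-seq, with 3 biological replicates per group and 18 libraries in all. Per the labels' protocols, RNA with s4UTP was biotinylated, enriched on magnetic beads and treated with iodoacetamide, and stranded libraries were made without polyA selection. Per the submitters' processing notes, the authors used Trimmomatic, HISAT, SAMtools, Picard, featureCounts and DESeq2, with versions not given in the sources used here, and the genome build GRCz11.

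The authors deposited a table of counts for 32520 genes and 4 tables of comparisons for 17135 genes each. The 18 count columns carry names that match no sample label, so their values were not used in any step, and only the gene symbols, coordinates, strand and exon length of that table were used. The results therefore rest on the 4 comparison tables, each of an injected group against untreated embryos of its stage. Their mean normalized count is a signal averaged over libraries by the authors, and it was identical in the 4 deposited tables. Their log2 fold changes and standard errors are shrunken estimates by the authors, judged from values near 0 beside small p-values. Their p-values and adjusted p-values are also the authors' own, and the deposited adjusted p equalled a Benjamini-Hochberg adjustment over the genes that kept an adjusted p. Whether the counts hold all reads or reads with converted bases is not given in the sources used here.

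The tests planned before the data were examined, count models on the libraries of each stage, need libraries mapped to groups and were not run. The same holds for the planned comparison of untreated embryos between stages, the gene-wise comparison of CDK9 with MiR430, the comparison of own calls with the deposited ones, and the level of cdk9 in each library. Depth per library was likewise not used here. No genome sequence was used, so microRNA seed matches in 3′ untranslated regions were not analysed here.

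A gene was called where the deposited adjusted p was under 0.05, and it rose or fell by the sign of its log2 fold change. The authors' own call column marked genes with an adjusted p under 0.01 and an absolute log2 fold change above 2, a rule with 0 mismatches over the 4 tables. In 139 genes no p was given. Symbols came from the count table through gene IDs because 13 symbols had turned into dates in the comparison tables, and 510 IDs had no symbol. A fold was given no size where the lower group would hold under 1 read over its 3 libraries even if all reads of the gene lay in the higher group.

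The 20 gene lists were fixed before the data were examined. They cover P-TEFb and pause release, early zygotic transcription factors, the dorsal organizer, Nodal and mesendoderm, Bmp and ventral genes, the yolk syncytial layer, the enveloping layer, maternal oocyte and germ plasm transcripts, pluripotency and chromatin activators, p53 response, heat shock, immediate early genes, interferon and RNA sensing, the cell cycle, splicing factors, documented miR-430 targets, ribosomal proteins, mitochondrially encoded genes, histones and mir-430 genes. Counts of risen or fallen members are given out of all measured members, and members without an adjusted p count as not passing. A signed z statistic was made from each deposited p and the sign of its log2 fold change. Lists of at least 5 tested genes were compared with all other tested genes by cameraPR of limma 3.58.1 in R 4.3.3, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. An estimated correlation needs values per library and was not run, and a preset of 0.05 was added in its place. In 100 simulated draws without effect on the 9124 genes of CDK9 at the 256-cell stage, 0% of list tests were called. Early zygotic factors moved by 1 standard error were called in 89% of draws. Genes were drawn independently, so these draws do not show the error rate where genes move together. For CDK9 at the 256-cell stage, 200 of 9124 simulated genes moved by 2 standard errors were recovered at 1%, by 4 at 76.5% and by 6 at 99.5%.

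Differences between stages and between injections were tested on lists from differences of z statistics. For CDK9, genes called at either stage were also tested through the difference of the deposited log2 fold changes over their combined standard error. These tests are approximate because shrunken estimates and differing precision enter them. Overlaps of calls were set beside independent lists and 100 simulations with shared controls. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.

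The genes named were cdk9 and the mir-430 genes, the 8 largest rises and 8 largest falls per comparison among called genes with a proper symbol, up to 4 members per list with the smallest adjusted p or the 2 most abundant where none passed, and 5 genes per direction for the stage difference. The planned minimum of normalized counts per library and the condition of no overlap between libraries need values per library, so a mean normalized count of at least 50 replaced both after the data were seen. The alternatives were no filter, a mean of at least 50, mitochondrially encoded genes left out, and a minimum log2 fold change of 1. Others were added after the data were seen, namely the authors' call, recentred statistics, histone and mir-430 copies left out, ranks, the larger preset correlation and the P-TEFb list without cdk9.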

Results

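RNA enriched for new transcripts, called new RNA here, was measured in whole wild type zebrafish (Danio rerio) embryos. The 2 stages of zygotic genome activation were the 256-cell and the 1024-cell stage. Embryos received the modified nucleotide s4UTP, which is built into RNA made after the injection. Labelled RNA was then captured through biotin, and its modified bases were converted chemically so that they read as point mutations (enriched SLAM-seq). There were 3 conditions, namely s4UTP alone (called untreated here), s4UTP with MiR430 microRNA, and s4UTP with cdk9 mRNA to overexpress CDK9, the kinase of the elongation factor P-TEFb. Each condition had 3 biological replicates per stage, which gives 18 libraries in 6 groups. No group received a control mRNA or a control microRNA. An effect of injected RNA as such therefore cannot be told apart from an effect of CDK9 or MiR430 in the comparisons with untreated embryos. The series concerns transcription bodies, nuclear sites of strong early transcription, and their relation to CDK9. All results below start from 4 comparisons that the authors deposited, each of an injected group against the untreated group of its stage.

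Mitochondrially encoded genes held 96.8% of the summed mean normalized count, and the 17098 nuclear genes had a median of 9.79 normalized counts per library. Only 2354 nuclear genes (13.8%) reached a mean of 50. The depth of single libraries was not used here, so the mean over all libraries stands for the depth behind each value. Log2 fold changes are the authors' shrunken estimates with their standard errors (SE), and they lie near 0 where shrinkage was strong. This was most marked for MiR430 at the 256-cell stage, where the median SE of tested genes was 0.02, against 0.33 to 0.59 in the other comparisons. Abundant genes lay near 0 there too, such as klf17 with a mean of 3213, a log2 fold change of 0.0036 and an unadjusted p of 0.0147 in the authors' deposited table. Most log2 fold changes of that comparison therefore do not measure the size of a change.

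Overexpression of CDK9 was visible in cdk9 itself. The gene (ENSDARG00000044811, chromosome 21, 6136981 to 6150568 in GRCz11, 8 exons) rose by 6.79 on the log2 scale (SE 0.41, adjusted p = 7.1e-59) at the 256-cell stage in the authors' deposited table. At the 1024-cell stage it rose by 5.88 (SE 0.39, adjusted p = 9.7e-50) in the authors' deposited table. Under MiR430, cdk9 had log2 fold changes of 0.0017 (adjusted p = 1) and 0.03 (adjusted p = 0.812) at the 256-cell and 1024-cell stages in the authors' deposited table. The value under MiR430 at the 256-cell stage comes from the strongly shrunken comparison and gives no size. Reads of the injected cdk9 mRNA are not separated from those of the embryo's own gene. If the rise came from the injected mRNA, RNA made before the injection also entered the counts, which was not tested.

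**Figure D1:**
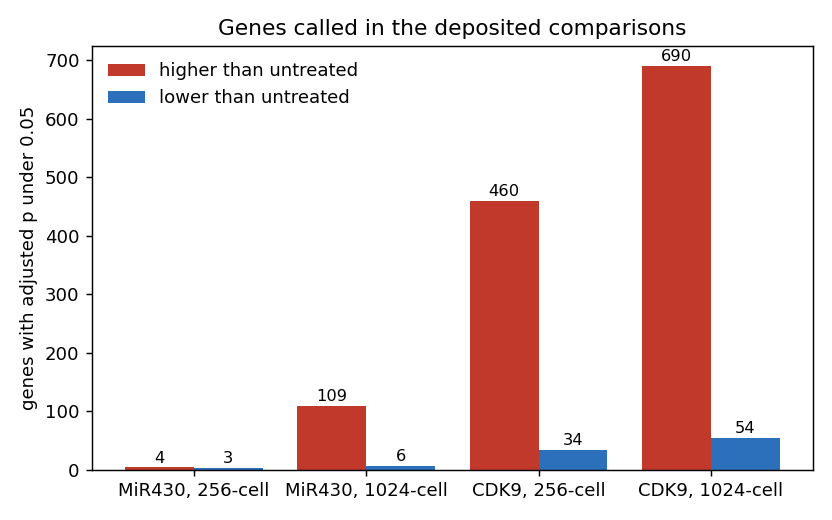
Number of genes (vertical axis) with an adjusted p under 0.05 in the authors' 4 comparisons against untreated embryos, with genes higher than untreated in red and lower in blue. CDK9 gave 460 and 690 rises at the 256-cell and 1024-cell stages, and MiR430 gave 4 and 109.

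The first comparison asked how CDK9 overexpression changes new RNA at the 256-cell stage. Most of the listed early zygotic transcription factors rose, and nearly all calls were upward. The Iroquois homeobox gene irx7 (chromosome 23, 37815645 to 37816969) rose by 7.93 (SE 1.18, adjusted p = 2.1e-09) and the Krüppel-like factor klf17 (chromosome 2, 33326522 to 33328688) by 6.76 (SE 1.11, adjusted p = 1.3e-07) on the log2 scale in the authors' deposited table. The Nodal ligand ndr1 (chromosome 21, 21010786 to 21013085) rose by 8.58 (SE 1.46, adjusted p = 1.3e-07) in the authors' deposited table. The cluster of mir-430 microRNA genes on chromosome 4 rose as well, with 36 of its 54 copies past the threshold. Across the 9124 genes tested, 460 rose and 34 fell at an adjusted p under 0.05 in the authors' deposited table.

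Of 23 measured early zygotic transcription factors, 14 rose, 0 fell and 9 did not pass at the 256-cell stage under CDK9. Adjusted over the list alone, 16 rose. Beside irx7 and klf17, the ventral repressor gene vent rose by 8.17 (SE 1.44, adjusted p = 4.3e-07) and the forkhead gene foxd5 by 8.88 (SE 1.65, adjusted p = 9.2e-07) in the authors' deposited table. The factor pou5f3, needed for genome activation, had a log2 fold change of 0.03 (SE 0.31, adjusted p = 0.968) in the authors' deposited table, a value named after it was seen. The list shifted upward against all other genes (limma camera, adjusted p = 1.3e-20).

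**Figure D2:**
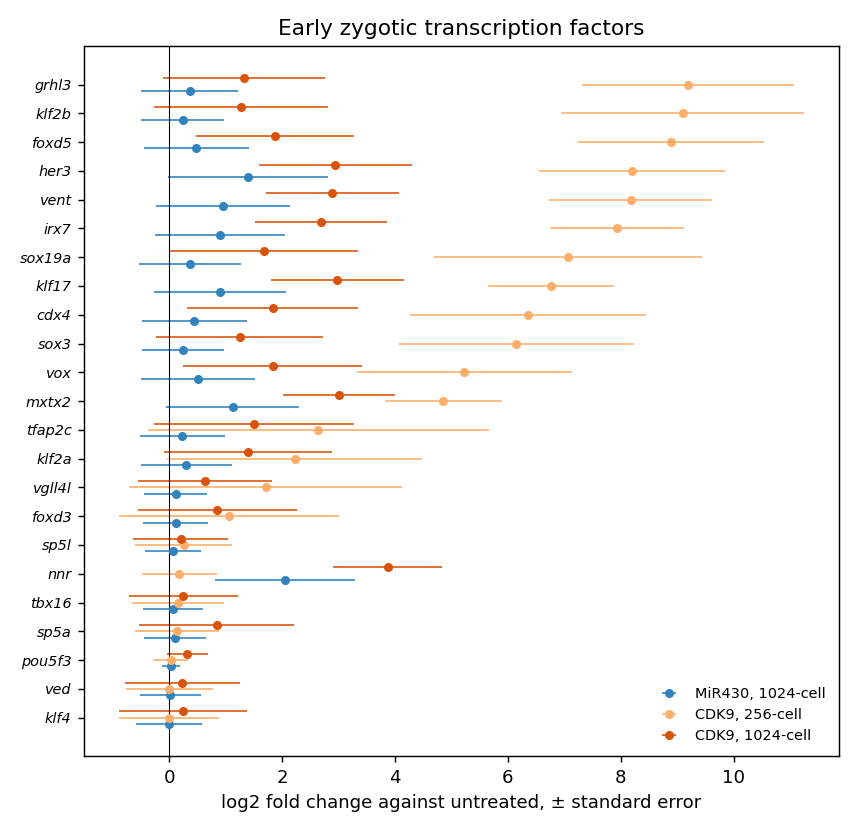
Log2 fold change against untreated embryos (horizontal axis) of 23 early zygotic transcription factors, as points with the authors' standard errors, for MiR430 at the 1024-cell stage and CDK9 at both stages. Under CDK9, 14 of the genes passed the threshold at the 256-cell stage and 6 at the 1024-cell stage.

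In the dorsal organizer list 6 of 19 measured members rose (9 adjusted over the list alone), in the Nodal and mesendoderm list 7 of 25 (8 adjusted over the list alone), and in the Bmp, ventral and ventrolateral list 6 of 19 (7 adjusted over the list alone). The Bmp antagonist gene chrd rose by 7.40 (SE 1.69, adjusted p = 9.4e-05) and the Nodal antagonist gene lft1 by 5.94 (SE 1.36, adjusted p = 0.00013) in the authors' deposited table. The GATA factor genes gata2a and gata3 rose by 7.94 (SE 1.99, adjusted p = 0.000177) and 6.58 (SE 1.60, adjusted p = 0.000219) in the authors' deposited table. The camera adjusted p was 2.6e-08, 6.2e-06 and 1.8e-08 for these lists in that order, all upward. The lists share members in every comparison, so their counts and tests are not independent. Among genes that rose here, vent, vox and cdx4 stand in both the Bmp list and the early zygotic list. The genes ndr1 and lft1 stand in both the dorsal organizer list and the Nodal list. Of 8 documented miR-430 targets 3 rose (3 adjusted over the list alone), namely ndr1, lft2 and lft1, which also stand in the Nodal list (camera adjusted p = 0.000514, and 0.104 with ranks).

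In the immediate early list 5 of 21 members rose (9 adjusted over the list alone), including the AP-1 gene fosab at 7.25 (SE 1.55, adjusted p = 4.2e-05) in the authors' deposited table. In the p53 response list 4 of 20 rose (5 adjusted over the list alone), with the cell cycle inhibitor gene cdkn1a at 6.94 (SE 1.57, adjusted p = 9.7e-05) in the authors' deposited table. Both lists shifted upward (camera adjusted p = 3.2e-05 and 0.000153). The interferon and RNA sensing list shifted upward (camera adjusted p = 0.00619) with 1 of 15 members past the threshold, irf7 at 5.61 (SE 2.91, adjusted p = 0.006) in the authors' deposited table. Among 56 histone genes 17 rose (20 adjusted over the list alone, where 1 also fell), including hist1h2a6 at 5.18 (SE 1.32, adjusted p = 0.000298) in the authors' deposited table, and the list shifted upward (camera adjusted p = 5.5e-05). Histone genes are short and often near identical, so reads may be split between copies.

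Several lists gave weaker results at this stage. In the P-TEFb and pause release list 2 of 32 members rose, cdk9 itself and the bromodomain gene brd2a at 6.46 (SE 0.86, adjusted p = 1.9e-11) in the authors' deposited table. That list passed with an adjusted p of 0.0351, and had an adjusted p of 0.128 with a preset correlation of 0.05. It includes cdk9, whose mRNA was injected, and without cdk9 it did not pass (adjusted p = 0.686). In the enveloping layer list 3 of 14 members rose (3 adjusted over the list alone, adjusted p = 0.0214, and 0.202 with a mean of at least 50 and 0.435 with ranks). In the yolk syncytial layer list 2 of 10 members rose (2 adjusted over the list alone, adjusted p = 0.0373, and 0.0639 with a preset correlation of 0.05). Both layer lists share members with the early zygotic factors, such as klf17, grhl3 and mxtx2. Of 18 pluripotency and chromatin activators 2 rose, sox19a and sox3, which also stand in the early zygotic list (adjusted p = 0.0215, and 0.0705 with a preset correlation of 0.05). Cell cycle genes (2 of 33 rose, adjusted p = 0.686), splicing factors (4 of 28 rose and 1 fell, adjusted p = 0.765), ribosomal proteins (3 of 81 rose, adjusted p = 0.0641) and heat shock genes (0 of 16, with 1 higher at an unadjusted p under 0.05, adjusted p = 0.659) did not shift as lists. Of the 81 ribosomal protein genes 44 kept an adjusted p at this stage, and of the 16 heat shock genes 8 did. The heat shock list had a positive mean statistic but lay below other genes in the test.

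Maternal oocyte and germ plasm transcripts, which stand for RNA loaded before fertilization, had 0 of 30 members past the threshold in the authors' deposited table, with 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.0805). The 13 mitochondrially encoded mRNAs had 0 calls and 0 at an unadjusted p under 0.05, with a median log2 fold change of -0.12 in the authors' deposited table. As a list they lay below other genes (camera adjusted p = 0.0431, and 0.105 with a preset correlation of 0.05).

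Among called genes with a proper symbol and a mean of at least 50, the largest rises with a size were the dre-mir-430c-1 copy at 28707457 to 28707529 on chromosome 4 at 10.08 (SE 1.61, adjusted p = 2.5e-09), the Grainyhead-like gene grhl3 at 9.19 (SE 1.87, adjusted p = 4.2e-06) and klf2b at 9.09 (SE 2.15, adjusted p = 4.4e-05) in the authors' deposited table. The genes akap12b, sb:cb81, znf1092 and fgfr4 rose too, but their untreated level lay under 1 read over the 3 libraries, so the listed fold has no size. The falls named here are the largest under the same limits, and less abundant genes fell further, so that the median of all 34 falls was -1.29 on the log2 scale in the authors' deposited table. The ubiquitin ligase gene cop1 fell by 1.46 (SE 0.64, adjusted p = 0.00746), the meteorin-like gene metrnla fell by 1.24 (SE 0.66, adjusted p = 0.0265) and the calmodulin gene calm3b fell by 1.22 (SE 0.55, adjusted p = 0.0181) on the log2 scale in the authors' deposited table. With the statistics recentred on their median, 302 genes rose and 65 fell, which is 82.3% upward against 93.1% before.

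The second comparison asked the same at the 1024-cell stage. Histone genes were the group with the most rises here, and smaller shares of the cell cycle, splicing, ribosomal protein and early zygotic lists rose. The histone gene hist1h2ba (chromosome 25, 35048945 to 35049318) rose by 6.25 on the log2 scale (SE 0.90, adjusted p = 4.0e-11) in the authors' deposited table. The replication helicase gene mcm5 rose by 3.20 (SE 0.63, adjusted p = 3.7e-05) and the splicing factor gene srsf5a by 3.56 (SE 0.75, adjusted p = 8.9e-05) in the authors' deposited table. Of 11724 genes tested, 690 rose and 54 fell in the authors' deposited table. With only genes of a mean of at least 50 tested, 405 rose and 30 fell.

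Of 56 histone genes 38 rose and 18 did not pass (44 rose adjusted over the list alone). Beside hist1h2ba, hist2h3c rose by 4.39 (SE 0.84, adjusted p = 8.4e-06) in the authors' deposited table. Copies named hist1h4l rose by 4.57 to 5.05 in the authors' deposited table, and reads may be split between them. The histone list had a camera adjusted p of 1.8e-36. In the cell cycle list 10 of 33 members rose (15 adjusted over the list alone), with the mitotic regulator gene fbxo5 at 3.67 (SE 0.82, adjusted p = 0.00015) in the authors' deposited table. Among splicing factors 8 of 28 rose (13 adjusted over the list alone), with the helicase gene ddx5 at 2.94 (SE 0.61, adjusted p = 0.000111) in the authors' deposited table. Among ribosomal proteins 14 of 81 rose (28 adjusted over the list alone), with rpl13a at 3.38 (SE 0.95, adjusted p = 0.00187) in the authors' deposited table. These lists shifted upward with camera adjusted p of 5.5e-07, 1.1e-06 and 9.5e-14. Of the 81 ribosomal protein genes 71 kept an adjusted p here, against 44 at the 256-cell stage, so their counts of rises are not directly comparable. With a mean of at least 50, 4 of the 5 ribosomal protein genes tested rose.

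The early zygotic factors had 6 of 23 members risen at this stage (15 adjusted over the list alone, camera adjusted p = 7.0e-09). They included nnr at 3.87 (SE 0.96, adjusted p = 0.000479), the yolk syncytial regulator mxtx2 at 3.01 (SE 0.99, adjusted p = 0.00553) and klf17 at 2.98 (SE 1.18, adjusted p = 0.0117) in the authors' deposited table. The dorsal organizer list had 7 of 19 members risen (10 adjusted over the list alone), the Nodal list 6 of 25 (10 adjusted over the list alone) and the Bmp list 4 of 19 (8 adjusted over the list alone). The Nodal cofactor gene foxh1 rose by 2.69 (SE 0.68, adjusted p = 0.00123) and ndr1 by 3.13 (SE 0.96, adjusted p = 0.00357) in the authors' deposited table. Their camera adjusted p were 7.7e-07, 4.4e-07 and 7.7e-06. With recentred statistics 4 dorsal organizer members rose. Pluripotency and chromatin activators had 4 of 18 members risen, including nanog at 1.99 (SE 0.60, adjusted p = 0.00435) in the authors' deposited table (camera adjusted p = 0.00631, and 0.0796 with a mean of at least 50).

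Immediate early genes (8 of 21 risen, adjusted p = 5.5e-07), the p53 response (6 of 20, adjusted p = 8.7e-05) and interferon and RNA sensing (3 of 15, adjusted p = 0.00048) shifted upward in the camera test. Adjusted over the list alone, 11, 7 and 5 of them rose, and 1 immediate early gene fell. With recentred statistics 3 p53 response members and 0 interferon members rose, and with a mean of at least 50 the counts for immediate early, p53 response and interferon genes were 5, 3 and 1. The phosphatase gene dusp1 rose by 3.34 (SE 0.81, adjusted p = 0.000595) and cdkn1a by 4.36 (SE 1.06, adjusted p = 0.000222) in the authors' deposited table. The yolk syncytial layer list (1 of 10 risen) passed at an adjusted p of 0.00631. Enveloping layer (2 of 14 risen), heat shock (1 of 16 risen, hspa5) and P-TEFb lists (3 of 32 risen, cdk9, brd2a and brd3a) passed at adjusted p of 0.0297, 0.0311 and 0.0332. Without cdk9, whose mRNA was injected, the P-TEFb list did not pass (adjusted p = 0.559). Without a filter and with recentred statistics brd3a lost its call. With a preset correlation of 0.05 those 3 lists had an adjusted p of 0.0651, 0.0665 and 0.13. Documented miR-430 targets did not shift as a list (adjusted p = 0.226), with ndr1, lft2 and, except without a filter or with recentred statistics, lft1 risen and the germ plasm gene tdrd7a fallen by 1.19 (SE 0.61, adjusted p = 0.0328) in the authors' deposited table.

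Maternal transcripts shifted downward as a list (camera adjusted p = 0.00664, and 0.0502 with a preset correlation of 0.05), and tdrd7a was their only member past the threshold, with 0 fallen adjusted over the list alone. Mitochondrially encoded mRNAs lay below other genes (camera adjusted p = 0.0152) with 0 calls, 0 at an unadjusted p under 0.05 and a median log2 fold change of -0.10 in the authors' deposited table. Within those limits metrnla had the largest fall, and it fell by 4.10 on the log2 scale (SE 0.66, adjusted p = 7.0e-08), while dpy19l1l fell by 2.25 (SE 0.92, adjusted p = 0.0173) and the kinase gene prkg1a fell by 2.00 (SE 0.74, adjusted p = 0.0125) in the authors' deposited table. The RNA-binding protein gene raver1 fell by 1.82 (SE 0.63, adjusted p = 0.00913) in the authors' deposited table. The median of all 54 falls was -2.23 in the authors' deposited table.

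**Figure D3:**
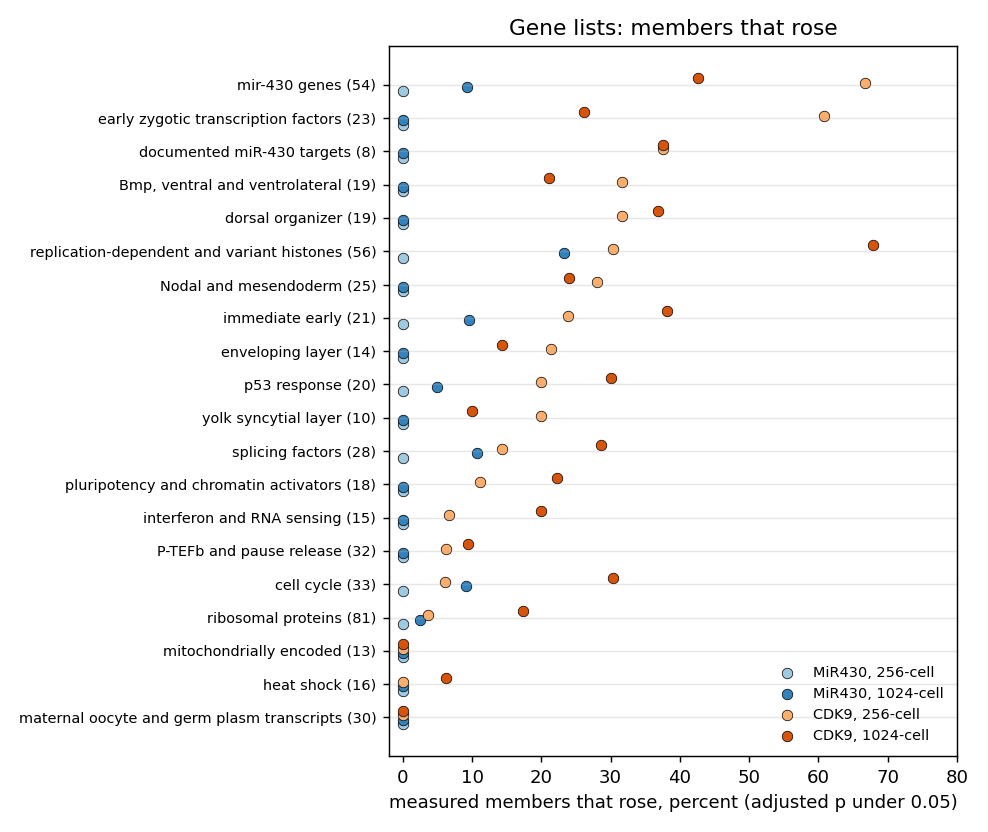
Share of the measured members of each fixed gene list that rose against untreated embryos (horizontal axis, percent), with the number of measured members in brackets and 1 point per comparison. Members without an adjusted p count as not risen. Under CDK9, mir-430 genes and early zygotic factors lead at the 256-cell stage and histones at the 1024-cell stage, where 38 of 56 rose.

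The third comparison asked whether extra MiR430 microRNA changes new RNA at the 256-cell stage. Few genes changed. The growth factor gene fgf20a (chromosome 1, 16393077 to 16394814) rose by 3.22 (SE 2.66, adjusted p = 0.0093), and brf2, which encodes an RNA polymerase III factor, fell by 1.85 (SE 2.19, adjusted p = 0.015) on the log2 scale in the authors' deposited table. The genes akap12b, znf1092 and CU182823.1 also rose, and esyt1a and tsc22d3 also fell, each against a level under 1 read over 3 libraries and so without a size. In all, 4 genes rose and 3 fell among 12373 tested. Of the 16996 genes with a p, which include genes without an adjusted p, 491 had an unadjusted p under 0.05 in the authors' deposited table. Every call of this comparison is named here, which goes beyond the rule for named genes, and CU182823.1, esyt1a and brf2 were chosen after their values were seen.

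No list had a member past the threshold, yet 5 lists shifted upward as a whole. Early zygotic factors (0 of 23 risen, 7 adjusted over the list alone, 9 higher at an unadjusted p under 0.05) had a camera adjusted p of 3.7e-13. The mir-430 genes (0 of 54, 14 adjusted over the list alone, 19 higher at an unadjusted p under 0.05) had one of 2.6e-23. With a mean of at least 50, 2 mir-430 copies rose. In the authors' deposited table irx7, chosen here after its value was seen, had an unadjusted p of 0.000229 and an adjusted p of 0.218. Ribosomal proteins, the dorsal organizer list and documented miR-430 targets passed at 0.00172, 0.016 and 0.0225, but had adjusted p of 0.107, 0.0842 and 0.0842 with a preset correlation of 0.05. They had 0 members past the threshold, with 1, 3 and 3 higher at an unadjusted p under 0.05. The other lists had adjusted p from 0.196 to 0.956, such as histones (0.517), the P-TEFb list (0.517) and maternal transcripts (0.69). For splicing factors and the p53 response the median log2 fold change was below 0 while the mean statistic was above 0.

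The fourth comparison asked this at the 1024-cell stage. A minority of histone, cell cycle and splicing genes rose, as did the immediate early gene fosab. The gene hist1h2ba rose by 4.05 (SE 0.86, adjusted p = 0.000139), the bromodomain gene brdt by 3.35 (SE 0.81, adjusted p = 0.00234) and fosab by 3.04 (SE 1.18, adjusted p = 0.0174) on the log2 scale in the authors' deposited table. Of 10748 genes tested 109 rose and 6 fell. The nuclear protein gene cdca7a fell by 1.12 (SE 0.43, adjusted p = 0.0367) in the authors' deposited table, a call lost without a filter on low counts. In place of 6 falls there was 1 without a filter and 1 with a mean of at least 50. By the call column of the authors' deposited table, 21 genes rose.

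Among histones 13 of 56 rose (25 adjusted over the list alone, camera adjusted p = 1.7e-21). In the cell cycle list 3 of 33 rose (5 adjusted over the list alone, camera adjusted p = 0.000163), mcm5 by 2.45 (SE 0.63, adjusted p = 0.00803), ccnb3 by 2.74 (SE 0.72, adjusted p = 0.00803) and fbxo5 by 2.67 (SE 0.87, adjusted p = 0.0174) in the authors' deposited table. In the splicing list 3 of 28 rose (7 adjusted over the list alone, camera adjusted p = 9.6e-05), with srsf5a at 2.70 (SE 0.76, adjusted p = 0.0101) in the authors' deposited table. With recentred statistics 1 splicing factor rose. Ribosomal proteins (2 of 81 risen, adjusted p = 8.1e-15), immediate early genes (2 of 21, adjusted p = 0.00012) and the p53 response (1 of 20, adjusted p = 0.00134) shifted upward. Adjusted over the list alone, 6, 3 and 3 of them rose. With a mean of at least 50, 0 of the 5 ribosomal protein genes tested rose. Early zygotic factors shifted upward too (0 of 23 risen, 6 adjusted over the list alone, 10 higher at an unadjusted p under 0.05, adjusted p = 6.2e-08). Among them klf17 had a log2 fold change of 0.89 (SE 1.17, adjusted p = 0.215) in the authors' deposited table. Dorsal organizer, Nodal, Bmp and interferon lists passed at 0.000139, 3.2e-05, 0.000231 and 0.00543, with 0 members past the threshold. Of their members 5, 7, 6 and 3 were higher at an unadjusted p under 0.05. Adjusted over the list alone, 3, 4, 0 and 0 rose. The P-TEFb (0.264), yolk syncytial layer (0.0995), enveloping layer (0.16), pluripotency (0.122), heat shock (0.251) and mitochondrial (0.255) lists did not pass by their adjusted p. Maternal transcripts shifted downward (adjusted p = 0.013, and 0.0834 with a preset correlation of 0.05), with 0 of 30 past the threshold and 1 lower at an unadjusted p under 0.05.

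The documented miR-430 targets, which the injected microRNA is known to repress, had 0 of 8 members past the threshold in this comparison (camera adjusted p = 0.19). Adjusted over the list alone 2 rose, and 2 were higher at an unadjusted p under 0.05. Their most abundant members, lft2 and lft1, had log2 fold changes of 1.35 (SE 1.27, adjusted p = 0.128) and 0.26 (SE 0.68, adjusted p = 0.571) in the authors' deposited table.

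The mir-430 genes form 1 cluster of 54 annotated copies of 73 to 82 bases on chromosome 4, from 28693371 to 28709534 in GRCz11. They held 3.75% of the nuclear mean normalized count. Copies are near identical, so the count of copies that passed is not a count of independent genes. Under CDK9, 36 copies rose at the 256-cell stage (44 adjusted over the list alone), by 2.98 to 10.08 on the log2 scale in the authors' deposited table, and 23 at the 1024-cell stage (39 adjusted over the list alone), by 2.27 to 4.60. Under MiR430, 5 copies rose at the 1024-cell stage (31 adjusted over the list alone), by 2.48 to 2.88 in the authors' deposited table. Reads of the injected MiR430 microRNA, if any entered the libraries, are not separated from those of the mir-430 genes. Whether they add to the values under MiR430 at either stage was not tested. With recentred statistics the copies that rose at the 1024-cell stage numbered 14 under CDK9 and 2 under MiR430. The list shifted upward in all 4 comparisons, with camera adjusted p of 7.2e-42 and 7.9e-21 for CDK9 and 2.6e-23 and 1.7e-24 for MiR430 at the 256-cell and 1024-cell stages. The test counts copies of 1 locus as separate genes, so these p are too small, and the same limit holds for histone copies.

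**Figure D4:**
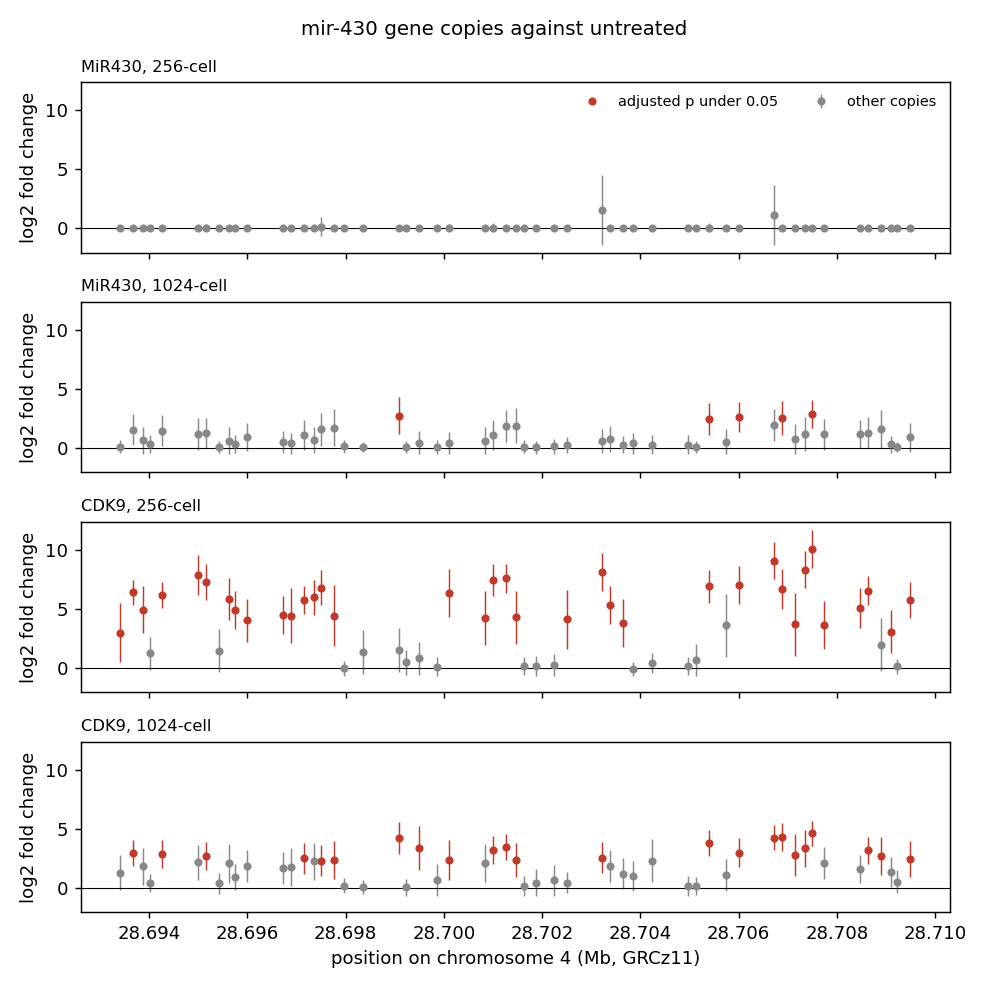
Log2 fold change against untreated embryos (vertical axis, with the authors' standard errors) of the 54 mir-430 gene copies along chromosome 4 (horizontal axis, Mb), 1 panel per comparison. Copies with an adjusted p under 0.05 are red, and they number 36 for CDK9 at the 256-cell stage.

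The MiR430 and CDK9 comparisons of a stage share their untreated libraries. At the 1024-cell stage 107 of the 109 genes that rose under MiR430 also rose under CDK9, among them hist1h2ba, mcm5, srsf5a and cdkn1a. Independent lists would share 6.99. In 100 simulations of unchanged groups 0 calls were shared with or without shared controls, so that count does not show how much the shared controls add. The covariance of the test statistics across genes was 1.34 against 0.502 in the simulation. At the 256-cell stage all 4 rises under MiR430 were shared with CDK9, where independent lists would share 0.202, but 3 of the 4 had an untreated level under 1 read over the 3 libraries. Of the 3 falls 1 was shared, brf2, and tsc22d3 fell under MiR430 and rose under CDK9. At the 256-cell stage the covariance was 0.56 against 0.5, but the correlation was 0.406 against 0.501 in the simulation. The correlation there did not exceed that of shared controls alone. At the 1024-cell stage it was 0.743 against 0.501. Part of the excess at the 1024-cell stage may come from the shared controls, which were not split here. Genes are not independent replicates in these covariances and correlations.

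The difference between the injections was tested on gene lists, from the difference of the statistics, in a test added after the data were seen. At the 256-cell stage mir-430 genes (adjusted p = 2.3e-14), early zygotic factors (2.4e-06), the Bmp list (4.3e-06), the dorsal organizer list (0.000126), immediate early genes (0.000126), histones (0.000126), the Nodal list (0.000261), the p53 response (0.00323) and interferon and RNA sensing (0.0228) lay higher under CDK9 than under MiR430. At the 1024-cell stage histones (adjusted p = 3.5e-12), the cell cycle (0.0344), the dorsal organizer list (0.0346) and immediate early genes (0.0346) did so, while early zygotic factors missed the threshold (0.0599). With a preset correlation of 0.05 histones stayed past the threshold (adjusted p = 3.3e-05), and the other 3 each had an adjusted p of 0.139.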

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

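The tests in this part were chosen after the results were seen, except that the bound for recentring was set before its outcome was known.

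What drew attention here were differences between the stages. For CDK9, list statistics at the 1024-cell stage minus those at the 256-cell stage were higher than in other genes for histones (adjusted p = 3.5e-13), ribosomal proteins (1.8e-06), the cell cycle (0.000137), splicing factors (0.000137) and heat shock genes (0.0257). They were lower for early zygotic factors (0.00549) and mir-430 genes (0.000738). For MiR430 the difference was upward for histones (6.0e-15), ribosomal proteins (0.000219), splicing factors (0.000891), the cell cycle (0.00448), immediate early genes (0.0179), the Nodal list (0.0179), interferon and RNA sensing (0.0179), the p53 response (0.0274) and mir-430 genes (0.0274), and downward for maternal transcripts (0.0179). With a preset correlation of 0.05, heat shock under CDK9 had an adjusted p of 0.0573, and under MiR430 only histones (2.1e-06) and splicing factors (0.0439) passed. A statistic also carries the precision of its comparison.

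Of 1014 genes called under CDK9 at either stage and measured on both sides, 62 had a larger log2 fold change at the 1024-cell stage and 8 at the 256-cell stage. At the 1024-cell stage hist1h4l (ENSDARG00000111165, adjusted p = 0.00197), hist1h2ba (0.00197), the methyltransferase gene nsun5 (0.00376), acin1a (0.00384) and golim4b (0.00902) were larger, by 4.69, 5.38, 4.68, 2.33 and 6.36 on the log2 scale. At the 256-cell stage grhl3 (adjusted p = 0.0262), foxd5 (0.0302), irx7 (0.0329) and ndr1 (0.0329) were larger, with differences of -7.86, -7.01, -5.24 and -5.46. The fall of metrnla was deeper at the 1024-cell stage (difference -2.86, adjusted p = 0.038). The rise of cdk9 itself did not differ past the threshold (difference -0.91, SE 0.56, adjusted p = 0.23).

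A first pattern to weigh is that genes that rose under MiR430 at the 1024-cell stage nearly all rose under CDK9 too. CDK9 at the 256-cell stage, which shares no library with MiR430 at the 1024-cell stage, had 35 of these rises, 6.49 times as many as independent lists. Independent lists are too low a standard, because rises were denser among abundant genes. Under CDK9 at the 256-cell stage 187 of 810 nuclear genes with a mean over 100 rose, against 56 of 3271 with a mean of at most 20. Histone and mir-430 copies made up 18 of the 109 rises under MiR430 and 53 of the 460 under CDK9. The ratio therefore does not decide whether sampling noise of the shared untreated libraries was the whole cause. Untreated embryos that were slightly younger or carried less new RNA could raise the same early genes in every injected group, and the upward shift of early zygotic factors under MiR430 at the 256-cell stage (limma camera, unadjusted p = 3.7e-14) leaves this open, as the values per library that would settle it were not used here. An effect common to both injections is open as well. An offset of the untreated embryos alone would act on both injections alike, while mir-430 genes and early zygotic factors lay higher under CDK9 than under MiR430 at the 256-cell stage. That difference does not address the timing or labelling of the CDK9 embryos themselves, which was not tested.

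A second pattern is that 93.1% and 92.7% of CDK9 calls at the 256-cell and 1024-cell stages were upward. After recentring, which takes the same amount from every statistic, at least 82.3% of calls stayed upward in both CDK9 comparisons. A scaling error would move each statistic by an amount that depends on its SE. Recentring therefore does not decide whether scaling played a part. Reads freed from mitochondrial transcripts would raise all nuclear genes alike. Nuclear genes with a mean of at least 50 had an upper quartile of log2 fold change of at most 0.57. The rises had a median of 3.45 at the 256-cell stage and 2.73 at the 1024-cell stage. These fold changes rest on normalized counts, where a rise shared by most genes would be taken out. They are also shrunken, and the rises were selected by their call. The values therefore do not decide whether freed reads played a part. Falls hidden by few untreated reads remain open as well. Among calls with a mean over 100 at least 97.4% were upward, but this decides nothing, because that mean includes the raised libraries. Of such rises, 57.8% at the 256-cell stage and 23.1% at the 1024-cell stage could have had an untreated level of at most 100.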

How the results depend on the processing

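The choices added after the data were seen were the authors' call, recentred statistics, histone and mir-430 copies left out, ranks, the larger preset correlation, the P-TEFb list without cdk9, and all settings of the overlap and of list members. The total number of calls of each comparison stayed within 1.5 times of that reported, with these exceptions, which follow from stricter thresholds or fewer genes tested. By the authors' call, MiR430 at the 1024-cell stage had 21 genes instead of 115, CDK9 at the 256-cell stage 232 instead of 494, and CDK9 at the 1024-cell stage 322 instead of 744, and MiR430 and CDK9 shared 20 genes at the 1024-cell stage instead of 107. With a mean of at least 50, CDK9 at the 1024-cell stage had 435 genes. Counts of falls and of list members moved more. Falls under MiR430 at the 256-cell stage went from 3 to 1 with a mean of at least 50. By the authors' call, risen early zygotic factors under CDK9 at the 1024-cell stage went from 6 to 2, mir-430 copies from 23 to 8, and histones under MiR430 at the 1024-cell stage from 13 to 4. For MiR430 at the 256-cell stage 5 lists passed, against 2 with a preset correlation of 0.05 and 3 with ranks, and the cause of the latter was not tested. Single lists lost their call in other settings too. With ranks these included the P-TEFb list under CDK9 at the 256-cell (adjusted p = 0.645) and 1024-cell stages (0.352), and with a mean of at least 50 ribosomal proteins under MiR430 at the 256-cell stage (0.962), pluripotency activators under CDK9 at the 256-cell stage (0.273), the enveloping layer under CDK9 at the 1024-cell stage (0.393), and maternal transcripts at the 1024-cell stage under MiR430 (0.107) and CDK9 (0.0696). With a mean of at least 50 the ribosomal protein list under MiR430 at the 256-cell stage held 5 genes. Without a filter the yolk syncytial layer list under CDK9 at the 256-cell stage had an adjusted p of 0.295. Recentring left 367 calls for CDK9 at the 256-cell stage, 302 up and 65 down against 460 and 34.

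Single genes were tested again under 5 alternatives. Of 396 pairs of a named gene and a comparison, 348 kept their side of the threshold wherever they were tested, and 0 changed direction while called. Not every pair was tested in each alternative, as genes dropped out with a mean of at least 50 or with copies left out. Of 205 named calls, 132 were kept by the authors' call, which lost klf17 under CDK9 and fosab under MiR430 at the 1024-cell stage, and 205 were kept with a minimum log2 fold change of 1. Testing without a filter ended 24 calls, recentring 27, and leaving out histone and mir-430 copies 6, while a mean of at least 50 added 14 calls. Without a filter lft1 and gata3 under CDK9 and ddx5 and hnrnpa1b under MiR430, each at the 1024-cell stage, lost their call, as did raver1 and srsf7a under CDK9 at the 256-cell stage. Leaving out mitochondrially encoded genes changed no named call.

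No paired analysis was possible because the columns with values per library carry names that match no label. For the same reason leaving out replicates, other normalizations, other count models, subsets of samples, other splits of the samples, an estimated correlation and the check for far-lying libraries were not run, so no statement is made about single libraries or about chance groupings of them. The median nuclear gene had 9.79 normalized counts, so small changes of most genes were not detectable at this depth.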

Other observations

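The tests here were chosen after the results were seen, except that the bound for strata of mean normalized count was set before its outcome was known.

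Genes on chromosome 4 were frequent among the rises under CDK9 at the 256-cell stage even without the mir-430 copies. They made up 55 of 407 rises (13.5%) against 4.17% of other tested genes (Fisher's exact test, two-sided, adjusted p = 9.6e-13 over 12 tests). Of these 55 genes, 47 start beyond 28 Mb, 16 carry a symbol starting with znf (zinc finger genes) and 32 have a clone name or no symbol. In the authors' deposited table znf1127 rose by 8.22 (SE 1.98, adjusted p = 0.000112) and znf1091 by 6.06 (SE 1.87, adjusted p = 0.00113), both chosen after their values were seen. At the 1024-cell stage chromosome 4 held 63 of 629 rises against 4.96% of other genes (adjusted p = 1.1e-06). Without genes whose symbol starts with znf, chromosome 4 still held 39 of the 407 rises at the 256-cell stage (9.58%, odds ratio 2.93 against other tested genes, adjusted p = 1.8e-07). Sharing of reads between near copies was not tested.

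Genes with 1 exon were also frequent among rises. Histone and mir-430 copies were left out by symbol, so histone copies with a clone name or no symbol may remain. Under CDK9, genes with 1 exon made up 12.8% of rises against 1.68% of other tested genes at the 256-cell stage (Fisher's exact test, adjusted p = 1.1e-25). At the 1024-cell stage they made up 15.3% against 1.56% (adjusted p = 2.5e-53). Under MiR430 at the 1024-cell stage they made up 13.2% of rises against 2.16% (adjusted p = 1.7e-06).

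Rises became less frequent with the genomic span of a gene, histone and mir-430 copies left out, and under CDK9 at the 1024-cell stage 28.9% of genes of up to 2 kb rose (95% Wilson interval 24.6% to 33.5%) and 1.07% of those over 50 kb (0.721% to 1.59%), and at the 256-cell stage 21.9% and 2.64% did. Copies known by symbol as histone or mir-430 genes are argued against as the whole cause. Without them, genes of up to 5 kb rose more often than genes over 20 kb at the 1024-cell stage (odds ratio 9.39). Histone copies with a clone name or no symbol may remain, so histone copies as such are not excluded. Within 10 strata of mean normalized count the odds ratio under CDK9 at the 1024-cell stage was 11.7 (95% interval 9.15 to 15.0). That mean includes the raised libraries, so these strata do not settle whether untreated read depth is a cause. The same direction under MiR430 at the 1024-cell stage (odds ratio 6.95) shows that the relation was not limited to CDK9, although both comparisons share untreated libraries at that stage. Short cell cycles, which may keep long genes from being finished before the next division, are a candidate explanation that was not tested.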
